A study of Arabidopsis thaliana with 28 samples.

How the data were processed

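The data were 28 ATH1 arrays of shoots and roots of Arabidopsis thaliana Col-0 at 7 times after wounding, in 14 groups of 2. The deposited values are intensity, 1 linear signal per probe set and array, made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. On every array the mean signal after leaving out the highest and lowest 2% lay between 100.007 and 100.01, so the deposited intensities were already scaled to a common level, and were used as they are. Scanner files and detection calls were not used here.

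The table held 22810 probe sets, of which 64 control probe sets (AFFX) were left out of all tests. Signals were taken to log2(signal + 10.7), the offset being the 25th percentile of all signals. This offset damps the noise of weak signals and understates their changes. A probe set was kept when its signal lay above the 40th percentile of its array on both arrays of at least 1 group, which left 16263. R 4.3.3 and limma 3.58.1 were used. The model had 1 mean per tissue and time point over all 28 arrays, with 14 residual degrees of freedom, and eBayes with trend and robust. Contrasts set each time against 24 h in the same tissue, the differences of these contrasts between tissues (interactions, with a moderated F-test over all 6), and the mean of the 7 shoot groups against that of the 7 root groups. Adjusted p-values are Benjamini-Hochberg values over the probe sets kept, with calls at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, trend.var on, for lists of at least 3 measured members, and adjusted over 108 tests; the same test with an estimated correlation is given beside each list called.

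Groups, contrasts, the filter, the offset, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The rule named, in each tissue and time against 24 h, the 5 largest rises and 5 largest falls among probe sets past the test with exactly 1 gene and both arrays on one side of both 24 h arrays, any member of a list, the 5 largest differences in each direction between the tissues and the 5 smallest p-values of the F-test. The text gives a choice of these. Genes were named from the platform annotation given for this work, in which 13513 probe sets have 1 gene, 503 several and 8794 are unnamed here; symbols of 13436 were updated through their Entrez gene to the TAIR10.1 RefSeq table. Of the probe sets kept, 8878 have 1 gene, and no gene was named from a probe set with several. Many well-known wound genes sit on probe sets unnamed here and are not reported. No coordinates are given, since the sources name no genome build.

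The lists covered jasmonate biosynthesis, JAZ repressors, jasmonate turnover, jasmonate responsive defence, rapid stress and touch, ethylene synthesis, abscisic acid and dehydration, salicylate, tryptophan and glucosinolate, phenylpropanoid and flavonoid, heat shock, morning clock, evening clock, photosynthesis, root markers, cell cycle and reference genes. Of 33 rapid stress genes 7 were measured, of 11 turnover genes 4 and of 21 photosynthesis genes 5, so a list stands for its measured members. RNA quality was read from the 3-prime to 5-prime ratios of the AFFX controls.

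The fit was tested on simulated data of 16263 probe sets, with measured means averaged over time in the tissue tested. In the contrast shoots 1 h against 24 h it recovered 89 of 100 probe sets changed by 1 (log2) and 100 of 100 changed by 2, with 7 false calls, and in roots 1 h against 24 h 92 and 99 of 100, with 17 false calls. In the unchanged contrast at 3 h there were 0 false calls in either tissue. Each simulated probe set had 1 measured spread for both tissues and independent normal noise. Similar recovery in both tissues was thus built in, and noise of single groups or correlated probe sets was not tested. Alternatives were quantile normalization, log2(signal + 1), no filter and a filter at the 60th percentile, eBayes without trend and robust, the replicate number as a block, only the arrays of the same tissue, 0.25 h as the reference, each array left out in turn, a threshold of 0.01 for the overlap and an estimated correlation for the lists. The mean of 3, 6 and 12 h as the reference for the early times was added after seeing the data.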

Results

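The data were transcript levels in shoots and roots of Arabidopsis thaliana accession Col-0 after mechanical wounding, measured on ATH1 microarrays. Wounding by puncture with pins began at day 16, after 3 h of light in a 16 h day, and plants were harvested 0.25, 0.5, 1, 3, 6, 12 and 24 h later. There were 28 arrays in 14 groups, 7 time points in each of the tissues, with 2 arrays per group. The question was how the transcriptome of each organ changes over the day after wounding. Unwounded plants were not analysed here, so each time point was compared with 24 h in the same tissue, which was taken at the same hour of the day as the start of the treatment. At 0.25, 0.5 and 1 h the plants were close to that hour, while at 3, 6 and 12 h time since wounding and time of day differed together. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels do not say which organ was punctured.

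Signals below are means with the SD over n = 2 arrays, and log2 changes are differences from 24 h with their SE from the fit; both are on the log2(signal + 10.7) scale where a log2 value is given, so changes of weak genes are understated. Signals below the 40th percentile of an array, which lay between 21.4 and 29.0, are close to the lowest levels measured. Of the 129 changes against 24 h given below for genes named by the rule or a list, 36 (22 rises and 14 falls) had their weaker side below that percentile on both arrays, among them all those of AT5G62360 and AT1G07050; their size depends on the offset, so they have no firm rank. The number of arrays limits the precision. The replicates of a group correlated across probe sets with r = 0.967 to 0.989 in shoots and 0.971 to 0.992 in roots; these are correlations across genes, which are not independent replicates. The median SD between replicates was 0.172 (log2) in shoots and 0.149 in roots.

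The 24 h shoot arrays stood apart in RNA quality. Their ratio of 3-prime to 5-prime signal of the actin control probe sets was 4.15 and 6.17, against 2.22 to 3.68 on the other 12 shoot arrays. The ratio for GAPDH was 1.32 and 1.59 against 1.07 to 1.28, and for ubiquitin 2.27 and 2.52 against 1.55 to 2.63. In roots the 24 h arrays lay within the range of the other 12 arrays for GAPDH and actin and ubiquitin alike, with actin ratios of 2.06 and 2.21 against 2.03 to 2.96. Every comparison of shoots with 24 h below uses those 24 h arrays as its reference.

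**Figure D1:**
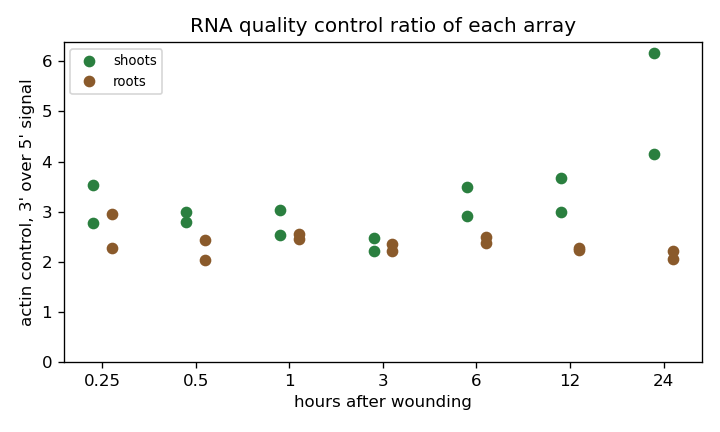
Ratio of the 3-prime to the 5-prime signal of the actin control probe sets on each array, by hours after wounding (each point is 1 array; green, shoots; brown, roots). The 24 h shoot arrays lie at 4.15 and 6.17, above all other arrays.

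Shoots and roots differed in most of the genes measured, and the tissue labels were matched by the markers. Photosynthesis genes were higher in shoots: PRK (phosphoribulokinase of the Calvin cycle) had a mean signal of 3957 ± 554 in shoots and 31.0 ± 9.42 in roots (SD over 14 arrays each), and LHCB4.1, LHCB4.2, RCA and SBPASE lay between 4.81 and 6.47 (log2) above roots. The root markers EXPA7, EXPA18, LBD16 and PYK10 were lower in shoots, by log2 changes of -1.38, -1.27, -1.30 and -1.73; PYK10, a beta-glucosidase of ER bodies, still had a signal of 1132 ± 452 in shoots against 3499 ± 306 in roots. Among the largest differences of genes with a name were AT1G23130 (7.19 ± 0.08), ECS1 (7.09), AT1G09310 (7.05), AT2G10940 (6.90) and PRK (6.60) in favour of shoots. In favour of roots they were AT4G15390 (-6.90 ± 0.08), AT4G30170 (-6.26), AT3G01190 (-6.18), AT4G39675 (-6.04) and AT3G13610 (-6.01). The limma fit called 14340 of 16263 probe sets at an adjusted p under 0.05, with 5087 higher in shoots and 9253 lower. The median over all probe sets was -0.27 (log2), so a probe set with no difference from the bulk sits slightly below 0; quantile normalization moved that median to -0.16 and gave 5852 higher among 14129 calls. The reference genes TIP41L, SAND and UBC21 lay at -0.63, -0.28 and -0.56.

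In shoots at 0.25 h, genes of rapid stress signalling stood far above their 24 h level. ZAT10 (AT1G27730), a zinc-finger transcription factor of stress responses, had a signal of 1987 ± 126 against 38.6 ± 2.86, a log2 change of 5.34 ± 0.26 (adjusted p = 1.2e-11). CML38 (AT1G76650), a calmodulin-like protein, reached 1013 ± 72.1 against 20.4 ± 17.1 (5.16 ± 0.79). ORA47 (AT1G74930), an AP2/ERF regulator of jasmonate synthesis, was at 741 ± 274 against 35 ± 10.1 (4.01 ± 0.30). The U-box ubiquitin ligases PUB23 and PUB22 rose by 3.57 and 2.43 and the transcription factor WRKY53 by 2.95.

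Of the 7 measured members of the rapid stress and touch list, 5 were higher in shoots at 0.25 h, both over all probe sets and adjusted over the list alone, with a median log2 change of 2.95; WRKY6 and PUB24 did not pass. The list's shift had an adjusted p = 8.79e-09 (camera), and adjusted p = 0.00578 with an estimated correlation. Outside the lists, AT4G29780 (5.12 ± 0.33), AT2G27080 (4.71 ± 0.32) and AT5G52050 (4.42 ± 0.49) were among the largest rises. The dehydrin COR47 was already higher, by 1.67 ± 0.20. It was not distinguished from its mean at 3, 6 and 12 h (below), in wounded plants at other times of day. Lower than at 24 h were the defensin PDF1.4 (-3.08 ± 0.46), the thionin THI2.1 (-1.64 ± 0.22), PYK10 (-1.38 ± 0.12), AT3G45210 (-1.80 ± 0.15) and AT4G12490 (-3.50 ± 0.75, with signals of 98.2 ± 134 against 596 ± 23.5). AT4G12490 and AT4G12500 are neighbouring members of 1 family and their probe sets may share signal. The change of AT4G12490 was -1.57 without shoots 0.25 h replicate 1 and -5.43 without shoots 0.25 h replicate 2. The median change over all probe sets was -0.092 (log2), and after quantile normalization 1698 of 3644 calls were higher. Among the 839 calls of at least 2-fold the balance was the reverse of that of all calls, with 586 higher and 253 lower. In all 3963 probe sets passed, 1615 higher and 2348 lower. Without shoots 24 h replicate 1 there were 2333, and with the mean of 3, 6 and 12 h as the reference, chosen after seeing the data, COR47 stood at 0.04 (adjusted p = 0.883) and was no longer called.

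At 0.5 h the signalling genes and a jasmonate synthesis gene were high in shoots. OPCL1 (AT1G20510), an acyl-CoA ligase of jasmonate synthesis and the measured member of its list of 16 genes, had a signal of 875 ± 98.6 against 95.1 ± 18.1 (3.07 ± 0.26, adjusted p = 3.03e-08). It was already higher at 0.25 h (2.25 ± 0.26), and its level at 0.5 h was not distinguished from that at 0.25 h (0.82, adjusted p = 0.0969). CML38 stood at 4.93 ± 0.79, PUB23 at 3.33 ± 0.23, and the glutaredoxin GRX480, the measured member of the salicylate list, at 2.56 ± 0.28. CML38 and PUB23 were not above their 0.25 h changes of 5.16 and 3.57. ZAT10 (3.70 ± 0.26) and ORA47 (1.84 ± 0.30) were above 24 h and below their own 0.25 h level, by log2 changes of -1.64 (adjusted p = 0.000669) and -2.16 (adjusted p = 0.000123) with 0.25 h as the reference. XTH18, a xyloglucan endotransglucosylase of cell walls, reached 644 ± 3.06 against 14.3 ± 9.19 (4.76 ± 0.45), AT1G15010 4.64 ± 0.33 and AT5G38700 4.51 ± 0.31. The levels of XTH18, AT1G15010 and GRX480 were not distinguished from those at 0.25 h, in plants already wounded (limma adjusted p = 0.776, 0.712 and 0.465). The rapid stress list had 6 of 7 members higher (6 also adjusted over the list alone) with a median of 2.03. Its camera adjusted p was 1.12e-06, and 0.0132 with an estimated correlation. The mean change of the list was 2.28, below the 2.85 at 0.25 h.

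Lower than at 24 h in shoots at 0.5 h were PDF1.4 (-3.69 ± 0.46), AT4G12500 (-3.22 ± 0.39) and JOX3 (AT3G55970), a jasmonate oxidase, at 7.89 ± 3.0 against 181 ± 95.3 (-3.28 ± 0.65). None of these 3 was distinguished from its 0.25 h level (limma adjusted p from 0.268 to 0.676 with 0.25 h as the reference). There were 4207 calls, 1784 higher and 2423 lower, and 1069 of at least 2-fold, 661 higher and 408 lower. The count was 2773 without shoots 0.5 h replicate 1 and 2416 without shoots 24 h replicate 1, with 1218 higher and 1198 lower. With 0.25 h as the reference 323 were higher and 280 lower.

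At 1 h the jasmonate turnover genes JOX2, JOX4 and JMT and the dehydration genes COR15A and COR47 were high in shoots. JOX2 and JOX4, oxidases that inactivate jasmonate, reached 2003 ± 15.5 against 265 ± 99.0 (2.92 ± 0.28) and 1330.3 ± 36.5 against 107 ± 19.7 (3.52 ± 0.64), and JMT, which methylates jasmonate, rose by 1.5 ± 0.29. COR15A (AT2G42540), a chloroplast protein of cold acclimation, stood at 1523 ± 176 against 47.7 ± 3.95 (4.71 ± 0.46, adjusted p = 6.77e-07) and COR47 at 3942 ± 134 against 243 ± 37.5 (3.97 ± 0.20). Both measured members of the abscisic acid and dehydration list were thus higher. OPCL1 stayed high (3.12 ± 0.26), and AT5G62360 (6.46 ± 0.60), AT1G51090 (4.78 ± 0.26), XTH18 (4.64 ± 0.45) and AT2G34930 (4.59 ± 0.42) were among the largest rises. XTH18 was not distinguished from its 0.25 h level (limma adjusted p = 0.744 with 0.25 h as the reference). ZAT10 was at 2.27 ± 0.26, below its 0.25 h change of 5.34.

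Of the 4 measured jasmonate turnover genes 3 were higher in shoots at 1 h, also adjusted over the list alone, and JOX3 did not pass. The list had a median of 2.21 and adjusted p = 0.0189 (camera), and adjusted p = 0.427 with an estimated correlation, which ends the call. It had adjusted p = 0.0711 without shoots 24 h replicate 2, with a mean change of 1.75 in place of 1.98, and adjusted p = 0.0584 with log2(signal + 1). The rapid stress list had a median of 1.39 with a camera adjusted p of 0.00317, and 0.162 with an estimated correlation. In this list 3 members were higher over all probe sets and 6 adjusted over the list alone. Its mean change was 1.23, below the 2.85 at 0.25 h. Lower were AT1G60590 (-3.46 ± 0.21), AT4G33666 (-3.36 ± 0.21), AT2G20670 (-3.17 ± 0.35) and the defensin PDF1.2 (-3.0 ± 1.0), whose 24 h signal varied widely (322 ± 265) and whose call ended without shoots 24 h replicate 1 (adjusted p = 0.232), without shoots 1 h replicate 1 (0.126) or replicate 2 (0.0815), and with only the shoot arrays in the fit (0.164). PDF1.2 did not pass with 0.25 h (0.19) or the mean of 3, 6 and 12 h (0.12) as the reference either, and with that mean neither did the turnover (0.0578) and rapid stress (0.0544) lists. Calls of at least 2-fold numbered 1383 at 1 h, 778 higher and 605 lower. With 5357 calls, 2359 higher and 2998 lower, 1 h had the most calls in shoots against 24 h. Against 0.25 h 1912 were higher and 1655 lower. With that reference 3, 6 and 12 h had more calls (4612, 5103 and 4819) than 1 h (3567).

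**Figure D2:**
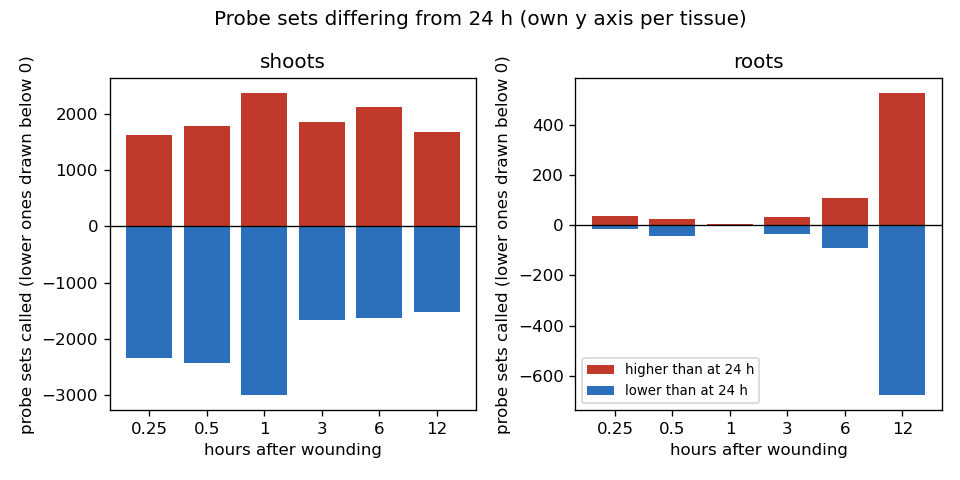
Number of probe sets called against 24 h at each time after wounding, with those higher above 0 and those lower below 0 (left, shoots; right, roots, on its own axis). Shoots had between 3194 and 5357 calls and roots between 9 and 1201.

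At 3 h COR15A and AT5G62360 were among the largest rises in shoots of genes with a name. AT5G62360 stood at 712 ± 61.1 against 5.81 ± 6.22, 5.50 ± 0.60. COR15A reached 3473 ± 321 (5.90 ± 0.46), its relative COR15B 529.9 ± 59.5 against 27.8 ± 0.576 (3.81 ± 0.25), the dehydrin LTI30 662 ± 28.3 against 27.3 ± 0.122 (4.15 ± 0.33) and AT4G30650 1722 ± 75.8 against 35.4 ± 16.0 (5.28 ± 0.29). JOX4 was at 3.74 ± 0.64 and JOX2 at 1.2 ± 0.28, which had an adjusted p of 0.0657 without shoots 24 h replicate 2. AT1G55960 (-2.20 ± 0.13), AT2G27420 (-2.99 ± 0.22), AT5G42760 (-2.48 ± 0.17) and the Calvin cycle gene SBPASE (-0.91 ± 0.18) were lower. The fit gave 3522 calls, 1860 higher and 1662 lower. The count was 2231 without shoots 3 h replicate 1, 1945 without shoots 3 h replicate 2 and 2221 without shoots 24 h replicate 1, and time of day is part of this comparison.

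At 6 h the clock gene GI (AT1G22770), the measured member of the evening clock list, was higher in shoots, at 372 ± 9.89 against 67.1 ± 15.5 (2.31 ± 0.20, adjusted p = 9.98e-09). Among the largest rises of genes with a name were AT5G62360 (1200.0 ± 39.8 against 5.81 ± 6.22, 6.25 ± 0.60), AT4G30650 (5.47 ± 0.29), AT1G07050 (444 ± 52.3 against 10.1 ± 3.35, 4.46 ± 0.24), AT1G56300 (4.27 ± 0.15) and COR15B (4.23 ± 0.25). AT1G55960 (121 ± 24.8 against 2208 ± 63.1, -4.09 ± 0.13), AT2G27420 (-3.86 ± 0.22), AT1G64500 (-3.72 ± 0.22), AT3G28270 (-3.65 ± 0.25) and AT2G15020 (-3.63 ± 0.22) were among the largest falls. The weaker side lay below the 40th percentile on both arrays for AT5G62360 and AT1G07050 (24 h) and for AT2G27420, AT1G64500 and AT2G15020 (6 h), so the order of these changes is not firm. Of the 5 photosynthesis genes 3 were lower, SBPASE (-0.97 ± 0.18), RCA (-0.56 ± 0.18) and PRK (-0.49 ± 0.17), and the list as a whole did not pass (camera adjusted p = 0.0667). RCA and PRK were not called after quantile normalization, at -0.34 (adjusted p = 0.152) and -0.21 (adjusted p = 0.324). The call of RCA ended without shoots 6 h replicate 2 (adjusted p = 0.188), shoots 24 h replicate 1 (0.061) or shoots 24 h replicate 2 (0.128). That of PRK ended without any of the 4 arrays of the comparison, with adjusted p-values of 0.0673 and 0.235 (6 h replicates 1 and 2) and 0.0574 and 0.219 (24 h replicates 1 and 2). PRK was also lost with log2(signal + 1) (0.102), with no filter (0.0562), without trend and robust (0.0534) and with the replicate block (0.0502), and with 0.25 h as the reference both RCA (0.12) and PRK (0.708) were. The fit gave 3750 calls, 2121 higher and 1629 lower; after quantile normalization 1792 were higher and 1797 lower.

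Among the largest rises in shoots at 12 h were AT1G07050 (3.82 ± 0.24), AT4G16146 (367 ± 21.8 against 16.9 ± 1.31, 3.78 ± 0.17), AT4G34950 (3.73 ± 0.66), AT4G30650 (3.51 ± 0.29) and AT2G23910 (3.36 ± 0.17), and the transcription factor WRKY6 was higher by 1.08 ± 0.20. The light-harvesting gene LHCB4.2 was lower, at 1538 ± 44.5 against 5772 ± 267 (-1.90 ± 0.20), the only call among the 5 photosynthesis genes. The thionin THI2.2 (-2.99 ± 0.23), SAG29, a sugar transporter of senescing leaves (-2.85 ± 0.23), and AT1G55960 (-3.93 ± 0.13) were lower too. The fit gave 3194 calls, 1667 higher and 1527 lower. The count was 1861 (914 higher and 947 lower) without shoots 12 h replicate 1 and 2087 without shoots 24 h replicate 1.

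**Figure D3:**
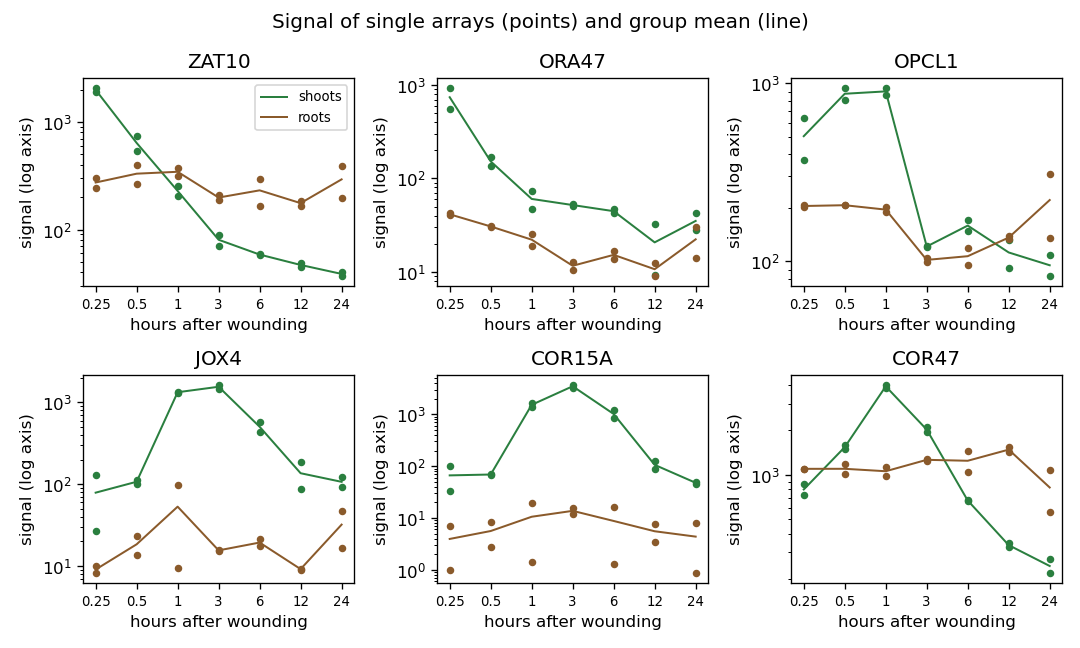
Signal (log axis) of 6 genes by hours after wounding in shoots (green) and roots (brown); points are single arrays and lines join the group means. In shoots ZAT10 and ORA47 are highest at 0.25 h, OPCL1 and COR47 at 1 h, and JOX4 and COR15A at 3 h.

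The time of the highest mean varied between genes in shoots. Of the 3319 probe sets higher than at 24 h at 0.25, 0.5 or 1 h, 727 had their highest mean at 0.25 h, 661 at 0.5 h, 1323 at 1 h, 241 at 3 h, 236 at 6 h and 131 at 12 h. Choosing them by their early levels favours early peaks and leaves none at 24 h, so these counts describe the set and test no order.

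In roots few probe sets passed at 0.25, 0.5 and 1 h against 24 h, with 51, 68 and 9 calls. This depends on the reference: against the mean of 3, 6 and 12 h, chosen after seeing the data, there were 758, 949 and 734. That mean averages more arrays and is of plants at other times of day. At 0.25 h AT1G52060 (670.3 ± 62.8 against 153 ± 91.4, 2.17 ± 0.34), AT1G52050 (1.94 ± 0.25) and AT3G19430 (1.85 ± 0.20) were higher than at 24 h. AT4G33720 (-1.75 ± 0.28) and ICL, isocitrate lyase of the glyoxylate cycle (-1.32 ± 0.24), were lower. None of the 7 rapid stress genes passed in roots (median 0.01, camera adjusted p = 0.974). The fit gave 51 calls, 37 higher and 14 lower. The count was 32 (11 higher and 21 lower) without roots 0.25 h replicate 1, 25 (11 and 14) without roots 0.25 h replicate 2, 134 without roots 24 h replicate 1 and 80 without roots 24 h replicate 2. Leaving out roots 0.25 h replicate 1 ended the calls of AT4G33720 (adjusted p = 0.0667) and ICL (0.171), leaving out roots 24 h replicate 1 that of ICL (0.0986), and leaving out roots 0.25 h replicate 2 that of AT1G52060 (0.0801). These 3 calls also ended with only the root arrays in the fit (adjusted p from 0.0776 to 0.118) and, with that of AT1G52050, with log2(signal + 1) (0.0597 to 0.169). Without roots 24 h replicate 2 AT4G33720 stood at -1.09 and was still called.

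At 0.5 h in roots the largest falls among genes with a name were of genes encoded in the plastid: rps4 (152 ± 45.0 against 498 ± 89.3, -1.67 ± 0.28), rps2 (-1.42 ± 0.27) for ribosomal proteins, psaA (-1.29 ± 0.26) and psbZ (-1.15 ± 0.24) for the photosystems, and cemA (-1.19 ± 0.20) for an envelope protein. EXPB2, a beta-expansin of cell walls (229 ± 65.0 against 69.5 ± 5.99, 1.56 ± 0.21), and AT1G52060 (1.76 ± 0.34) were higher. There were 68 calls, 25 higher and 43 lower. Without roots 0.5 h replicate 2 there were 4 calls and none of these plastid genes passed (adjusted p from 0.165 for cemA to 0.491 for psbZ); AT1G52060 had an adjusted p of 0.27. AT1G52060 and psaA were also lost without roots 0.5 h replicate 1 (0.105 and 0.111), psaA and psbZ without roots 24 h replicate 1 (0.0903 and 0.0624), and AT1G52060, rps2, psaA and psbZ without roots 24 h replicate 2 (0.259, 0.133, 0.103 and 0.2). Without roots 24 h replicate 2 the change of AT1G52060 was 1.16. With only the root arrays rps4, psaA, cemA, psbZ and AT1G52060 did not pass (0.0738, 0.144, 0.0615, 0.158 and 0.15). With 0.25 h as the reference rps4, psaA and psbZ did not (0.0862, 0.568 and 0.0862), with the mean of 3, 6 and 12 h psaA, psbZ and AT1G52060 did not (0.0692, 0.107 and 0.0617), and with log2(signal + 1) AT1G52060 did not (0.277). The count was 34 without roots 0.5 h replicate 1, 182 (95 higher and 87 lower) without roots 24 h replicate 1, 38 (19 and 19) without roots 24 h replicate 2 and 40 (20 and 20) with only the root arrays.

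At 1 h in roots 9 probe sets passed, 7 higher and 2 lower. The genes with a name among the rises were AT5G44730 (1.53 ± 0.28), AT5G59490 (1.32 ± 0.22), AT5G55050 (1.31 ± 0.23), AT4G14980 (1.03 ± 0.18) and AT1G27620 (0.97 ± 0.18). Their adjusted p-values lay between 0.0269 and 0.05, and none of the 5 passed without roots 1 h replicate 2, when the limma fit called 0 probe sets (1091 at an unadjusted p under 0.05; adjusted p from 0.258 to 0.444), or without roots 24 h replicate 2 (adjusted p from 0.0925 to 0.21). Without roots 1 h replicate 1 AT5G59490, AT5G55050, AT4G14980 and AT1G27620 were lost (0.071, 0.135, 0.0873 and 0.0568), and without roots 24 h replicate 1 AT5G44730 (0.0525). With the replicate number as a block AT5G44730, AT5G55050, AT4G14980 and AT1G27620 did not pass (adjusted p from 0.0522 to 0.0599), and none of the 5 did with only the root arrays (0.138 to 0.204) or with log2(signal + 1) (0.0852 to 0.448). With 0.25 h as the reference AT5G55050 (0.783) and AT4G14980 (0.0516) were lost and AT1G27620 changed sign (-0.26), and with the mean of 3, 6 and 12 h AT5G44730 was lost (0.062) and AT1G27620 stood at -0.55. The count was 3 without roots 1 h replicate 1, 122 without roots 24 h replicate 1 and 26 (13 higher and 13 lower) without roots 24 h replicate 2. The photosynthesis list lay at a median of -0.38 (camera adjusted p = 0.0189, and adjusted p = 0.612 with an estimated correlation), with 0 of 5 members called over all probe sets and 1 adjusted over the list alone; its adjusted p was 0.321 without roots 1 h replicate 1 and 0.295 without roots 24 h replicate 2. Its mean change was -0.39, and -0.24 and -0.22 without these arrays. The list did not pass with only the root arrays (0.0822), with 0.25 h as the reference (0.796) or with the mean of 3, 6 and 12 h (0.918).

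At 3 h in roots PDC2 (AT5G54960), a pyruvate decarboxylase of fermentation, was at 639.8 ± 112 against 177 ± 22.8 (1.79 ± 0.26). AT1G56300 (1.47 ± 0.15) and AT1G27620 (1.4 ± 0.18) were higher too, while AT1G74770 (-1.59 ± 0.23) and ccb452 (-1.16 ± 0.17) were lower. AT1G27620 did not pass with 0.25 h as the reference (adjusted p = 0.689). There were 65 calls, 31 higher and 34 lower, a balance that moved toward lower calls without roots 24 h replicate 2. The count was 11 (6 higher and 5 lower) without roots 3 h replicate 1, when PDC2, AT1G74770 and ccb452 had an adjusted p of 0.102, 23 without roots 3 h replicate 2, 117 (64 higher and 53 lower) without roots 24 h replicate 1, 165 without roots 24 h replicate 2 and 41 (22 and 19) with only the root arrays.

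At 6 h in roots AT4G33980 (129 ± 38.0 against 16.5 ± 8.58, 2.38 ± 0.24), COR27, a cold-regulated gene tied to the clock (2.18 ± 0.21), and AT1G56300 (1.68 ± 0.15) were higher. GI was higher as well (0.83 ± 0.20), with an adjusted p of 0.407 without roots 24 h replicate 1 and 0.273 without roots 6 h replicate 2. Without that 24 h array the change of GI was 0.52, and it did not pass with log2(signal + 1), no filter, eBayes without trend and robust or only the root arrays (adjusted p from 0.0511 to 0.0678). OCT1, an organic cation transporter (-2.13 ± 0.19), and AT1G74770 (-1.70 ± 0.23) were lower. There were 196 calls, 107 higher and 89 lower, 128 without roots 6 h replicate 1 and 333 (130 higher and 203 lower) without roots 24 h replicate 2; against 0.25 h 308 were higher and 327 lower.

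At 12 h in roots small heat shock proteins were among the largest rises. HSP17.6C (AT1G53540) had a signal of 478 ± 181 against 28.4 ± 15.6 (3.65 ± 0.66) and HSP22 of 162 ± 48.2 against 18.5 ± 9.50 (2.58 ± 0.41, adjusted p = 0.000617), so both measured members of the heat shock list were higher. AT2G29500 (3.57 ± 0.69) and AT1G52560 (2.96 ± 0.57), AT3G29970 (868 ± 175 against 92.3 ± 12.5, 3.08 ± 0.53) and AT5G10040 (2.91 ± 0.65) rose beside them, and COR47 by 0.91 ± 0.20. AT3G28510 (-3.06 ± 0.26), AT2G43590 (-2.50 ± 0.45) and OCT1 (-2.13 ± 0.19) were lower.

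Photosynthesis genes, markers of shoot tissue, were lower in roots at 12 h in 4 of 5 cases, and in 5 of 5 adjusted over the list alone: LHCB4.2 (-1.12 ± 0.20), RCA (-0.86 ± 0.18), PRK (-0.85 ± 0.17) and LHCB4.1 (-0.78 ± 0.22). The list had a median of -0.85 and adjusted p = 0.000121 (camera), and adjusted p = 0.427 with an estimated correlation, which ends the call. In all 1201 probe sets passed, 525 higher and 676 lower, and 388 by at least 2-fold. The count was 397 without roots 12 h replicate 1, 799 without roots 12 h replicate 2 and 610 without roots 24 h replicate 1. Without roots 12 h replicate 1 the adjusted p-values of HSP17.6C, AT2G29500, AT1G52560 and AT5G10040 were 0.053, 0.0649, 0.0625 and 0.103, and those of LHCB4.1, RCA and PRK 0.372, 0.103 and 0.0573. COR47 had an adjusted p of 0.0809 without that array and 0.131 without roots 24 h replicate 2. LHCB4.1 and RCA were also lost without roots 24 h replicate 2 (0.191 and 0.0741), and AT5G10040 without roots 24 h replicate 1 (0.0538) or replicate 2 (0.0616). The change of COR47 was 1.39 without roots 24 h replicate 1 and 0.44 without replicate 2, and that of LHCB4.1 -0.51 without roots 12 h replicate 1. With only the root arrays AT5G10040 (0.0728) and LHCB4.1 (0.0929) did not pass, and with 0.25 h as the reference COR47 (0.253), LHCB4.1 (0.051), RCA (0.0733) and PRK (0.414) did not.

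**Figure D4:**
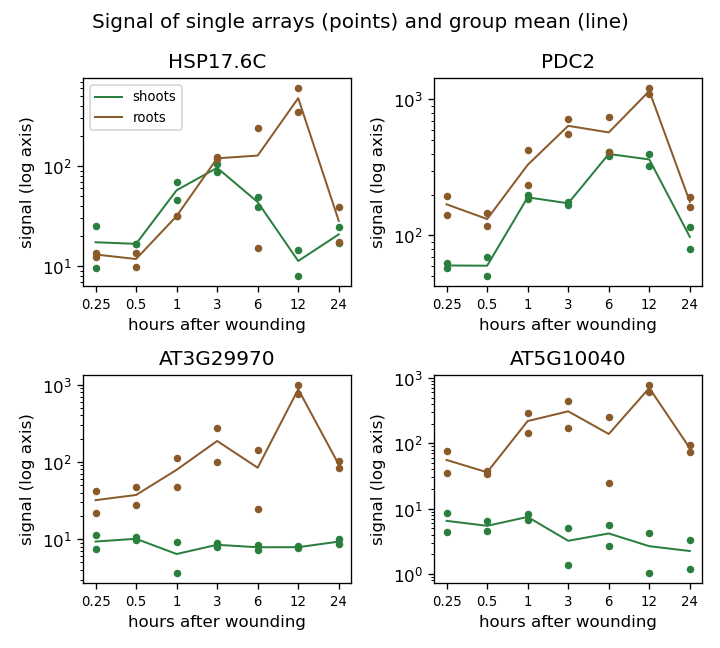
Signal (log axis) of 4 genes by hours after wounding in shoots (green) and roots (brown); points are single arrays and lines join the group means. In roots all 4 have their highest mean at 12 h.

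Whether the course over time differed between the tissues was tested by the interaction of tissue and time. The probe sets with the smallest p and a single gene were AT1G55960, AT1G19960, AT1G65490, AT1G33760 and AT2G24600. AT1G55960 fell in shoots by 4.09 (log2) at 6 h and lay at 0.07 in roots, while AT1G33760 stood at 3.64 in shoots at 0.25 h and at -0.01 in roots. The rapid stress list differed between the tissues at 0.25 h, with a mean difference of 2.81 (camera adjusted p = 4.47e-10, and adjusted p = 0.00519 with an estimated correlation), and at 0.5 h, with 2.19 (adjusted p = 1.64e-06, and adjusted p = 0.0132 with an estimated correlation). The jasmonate turnover list differed at 1 h by 2.03 (adjusted p = 0.0189, and adjusted p = 0.427 with an estimated correlation), and by 1.81 (adjusted p = 0.0711) without shoots 24 h replicate 2. The moderated F-test over the 6 interactions called 6871 of 16263 probe sets.

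The genes called in shoots and in roots overlapped beyond independent lists at 3, 6 and 12 h, and at 0.25, 0.5 and 1 h, with few root calls, no excess was detected. At 6 h 72 probe sets were higher in both tissues, where independent lists would share 13.95, among them COR27, AT1G56300, AT4G33980 and GI, and 31 were lower in both against 8.91. At 12 h 108 were higher in both against 53.8 and 181 lower against 63.5, and at 3 h 16 against 3.55 and 11 against 3.47. At 0.25 h 4 higher probe sets were shared against 3.67 and 2 lower against 2.02, at 0.5 h 1 against 2.74 and 8 against 6.41, and at 1 h 1 against 1.02 and 0 against 0.369. Fisher's exact tests, 1-sided, gave adjusted p-values between 7.59e-40 and 0.000759 at 3, 6 and 12 h and between 0.524 and 1 at 0.25, 0.5 and 1 h, over 12 tests; probe sets are not independent, so these describe the lists. The tissues share no arrays, but the fit pools the spread of both for each probe set. A low pooled spread eases calls in both tissues and can raise the overlap.

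The remaining lists had few measured members. Of the jasmonate responsive list, ORA47, PDF1.2 and THI2.1 were measured and no shift of the list passed; at 0.25 h in shoots its median was -1.03 and its mean 0.45, opposite in sign. The tryptophan and glucosinolate genes UGT74B1 and BCAT4 stood at 0.66 ± 0.19 in shoots at 1 h and at -0.97 ± 0.19 in shoots at 0.5 h, and the flavonoid gene DFR at -1.14 ± 0.29 in shoots at 6 h, each past the test. BCAT4 was also lower in shoots at 0.25 h (-0.85) and 12 h (-0.84). UGT74B1 was lost without shoots 1 h replicate 2 (adjusted p = 0.0664) or shoots 24 h replicate 1 (0.0853), and DFR without shoots 6 h replicate 1 (0.0657). BCAT4 was lost at 0.25 h without shoots 0.25 h replicate 2 (0.059), and at 0.25 and 12 h without shoots 24 h replicate 2 (0.0506 and 0.06). Of the root markers PYK10 was the member that changed in shoots, and 0 of the 4 were called in roots at any time. Of the reference genes UBC21 was higher in shoots from 1 h on, by 0.53, 0.63, 0.47 and 0.60 at 1, 3, 6 and 12 h, while TIP41L and SAND were not called. Without shoots 24 h replicate 1 UBC21 was lost at 1, 6 and 12 h (0.0765, 0.179 and 0.0574), with a change of 0.30 at 6 h, and without shoots 6 h replicate 1 at 6 h (0.107). With 0.25 h as the reference none of these 4 UBC21 calls held (adjusted p from 0.0771 to 0.423), nor did DFR at 6 h (0.29) or BCAT4 at 0.5 h (0.849) and 12 h (0.989). The JAZ, ethylene synthesis, morning clock and cell cycle lists had 0 members on a probe set with a name.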

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

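Of the tests below, the comparison of the spread in roots with that in shoots and the ratio of shoots to roots calls without the 24 h arrays were chosen only after the result was seen. Each result here stands out because the difference from 24 h was unlike in shoots and roots in a test of the interaction (adjusted p under 0.05). That test includes the 24 h shoot arrays, which stood apart in RNA quality, and time of day at 3, 6 and 12 h. It was not rerun with another reference. For single probe sets (limma) that test called 6871 probe sets over all times together. At 0.25, 0.5, 1, 3, 6 and 12 h it called 1534, 1857, 2617, 1371, 2074 and 1942. Each of these counts rose without shoots 24 h replicate 2. Leaving out roots 3 h replicate 1 brought the 3 h count to 679 and leaving out roots 0.25 h replicate 1 brought the 0.25 h count to 923. The 0.5 h count was 1205 without roots 0.5 h replicate 2 and the 1 h count 1732 without roots 1 h replicate 2. The lists were compared with camera. Among them, the mean difference of shoots minus roots was 2.81 for rapid stress at 0.25 h, 2.19 for rapid stress at 0.5 h and 2.03 for jasmonate turnover at 1 h. With an estimated correlation their adjusted p-values were 0.00519, 0.0132 and 0.427, so the turnover list was lost, as it was without shoots 24 h replicate 2 (adjusted p = 0.0711).

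The genes named for shoots differed from roots by the following log2 differences of the changes (shoots minus roots). At 0.25 h these were ZAT10 5.36, CML38 4.84, ORA47 3.30, WRKY53 2.93, PUB23 3.24, PUB22 2.19, AT4G29780 4.24, AT2G27080 3.94, AT5G52050 4.89, COR47 1.18 and OPCL1 2.25, and on the side of roots AT3G45210 -1.39, THI2.1 -1.59 and PYK10 -1.19. At 0.5 h they were CML38 4.69, XTH18 3.75, AT1G15010 4.45, AT5G38700 4.43, OPCL1 3.06, GRX480 2.36, ZAT10 3.48, ORA47 1.47 and PUB23 3.37, and on the side of roots PDF1.4 -2.93, AT4G12500 -3.49 and BCAT4 -0.99. At 1 h the list was AT5G62360 5.56, AT1G51090 4.86, COR15A 4.32, AT2G34930 4.55, OPCL1 3.18, JOX2 2.86, JOX4 3.30, JMT 1.72, COR47 3.54, ZAT10 1.97 and XTH18 4.28, and on the side of roots AT1G60590 -3.04, AT4G33666 -3.36 and AT2G20670 -3.06. At 3 h the differences were COR15A 5.16, AT4G30650 4.19, LTI30 3.79, COR15B 4.2, JOX4 4.35, JOX2 1.77 and AT5G62360 5.03, and on the side of roots AT2G27420 -2.88, AT5G42760 -2.25 and AT1G55960 -2.26. For 6 h they amounted to AT1G07050 4.37, AT1G56300 2.59, COR15B 4.41, GI 1.48, AT5G62360 5.07 and AT4G30650 4.54, and on the side of roots AT1G55960 -4.16, AT1G64500 -3.16, AT3G28270 -3.96, AT2G15020 -3.63, SBPASE -0.83, DFR -1.47 and AT2G27420 -3.97. For 12 h the values were AT4G16146 3.64, AT2G23910 0.97, WRKY6 1.24, UBC21 0.58, AT1G07050 3.47 and AT4G30650 3.17, and on the side of roots AT1G55960 -3.86, THI2.2 -2.95, SAG29 -2.80 and BCAT4 -1.42.

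The genes named for roots differed as well, again as shoots minus roots, so a negative value means a larger change upward in roots. The 0.25 h genes gave AT4G33720 1.5 and ICL 1.36 and, below 0, AT1G52060 -1.98, AT1G52050 -2.23 and AT3G19430 -2.02. The 0.5 h genes gave rps4 2.0, rps2 1.64, psaA 1.83 and cemA 0.89 and, below 0, EXPB2 -1.25 and AT1G52060 -1.87. Those of 1 h gave AT5G44730 -1.62, AT5G59490 -0.94, AT4G14980 -1.25 and AT1G27620 -1.07. Those of 3 h gave AT1G56300 1.25 and AT1G74770 1.59 and, below 0, AT1G27620 -1.51. For 6 h the differences were COR27 1.61, AT1G56300 2.59, GI 1.48, OCT1 2.08 and AT1G74770 1.70. For 12 h they were AT3G28510 4.01, AT2G43590 2.81 and OCT1 2.06 and, below 0, HSP17.6C -4.18, HSP22 -2.99, AT2G29500 -3.79, AT1G52560 -3.06 and AT3G29970 -3.19.

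Many more probe sets passed in shoots (3194 to 5357) than in roots (9 to 1201). Root replicates did not spread more than shoot replicates, with a median SD 0.865 times that in shoots. The fit pools the spread of both tissues for each probe set. This ratio therefore does not say whether noise in single root groups hides calls. Of the root groups, the 24 h reference had the largest SD of the difference between replicates across probe sets (0.346, and 0.358 for shoots 24 h). The RNA quality of the 24 h shoot arrays as the whole cause needs the gap to close without those arrays, and over the 8 comparisons with another reference shoots still had at least 4.55 times as many calls as roots. A stricter bound set beforehand, that each of the 8 shoots counts stay above 1201, was missed by 0.5 h against 0.25 h. That comparison gave 603 calls between groups that lie close in time. At every time the shoots counts against 24 h fell further without shoots 24 h replicate 1 than without replicate 2. Replicate 1 had the highest actin ratio of all arrays (6.17). At 0.25 and 0.5 h most of the calls lost with it were lower calls. A contribution of RNA quality to part of the shoots calls therefore stays open. The tissue itself, and which organ was punctured, may account for the gap and were not tested.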

How the results depend on the processing

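The alternative chosen after seeing the data was the mean of 3, 6 and 12 h as the reference. Over all other settings the shoots counts stayed within 1.5 times of those reported, apart from those below. Arrays left out leave a group with 1 array, which is assumed to vary like the other groups. Signal over background limits the weak genes, whose changes are understated. The cause of the moves was not tested, except where the reference, the arrays or the threshold changed, which alters the comparison itself.

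The roots 1 h count was 21 after quantile normalization, 3 with log2(signal + 1) and 0 with only the root arrays (limma; 1751 at an unadjusted p under 0.05). The roots 0.25 h count was 22 with log2(signal + 1), 32 with the stricter filter and 29 with only the root arrays, which gave 40 at 0.5 h and 41 at 3 h. The replicate numbers do not pair the arrays: over 91 pairs of groups the deviations of same-numbered arrays correlated between -0.277 and 0.190. With the replicate number as a block the roots 1 h count was 3.

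With 0.25 h as the reference the shoots counts were 603 at 0.5 h, 3567 at 1 h and 4819 at 12 h, and the roots counts 32, 134, 577 and 635 at 0.5, 1, 3 and 6 h. BCAT4 at 12 h in shoots then lay at 0.0045. The change turned negative for these: at 0.5 h CML38 -0.23, ZAT10 -1.64, ORA47 -2.16, PUB23 -0.24 and the mean of the rapid stress and touch list -0.57, at 1 h ZAT10 -3.07 and that list -1.62, and in roots AT1G52060 -0.41 at 0.5 h and AT1G27620 -0.26 at 1 h. With the mean of 3, 6 and 12 h as the reference the roots counts were 758, 949 and 734 at 0.25, 0.5 and 1 h, and at 1 h AT1G27620 stood at -0.55 and UBC21 in shoots at -0.034.

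At an adjusted p under 0.01 in both tissues the overlap of higher calls was 0 at 0.25, 0.5 and 1 h, 4 at 3 h, 33 at 6 h and 38 at 12 h. That of lower calls was 2 at 0.25 h (0.364 for independent lists, adjusted p = 0.0784), 0 at 0.5 h, 3 at 3 h, 16 at 6 h and 70 at 12 h. No root probe set passes that threshold at 1 h (limma; 1476 at an unadjusted p under 0.05), and fewer probe sets pass it at any time.

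With 1 array left out, the shoots counts ranged from 2333 to 3797 at 0.25 h, 2416 to 4159 at 0.5 h, 1945 to 3192 at 3 h and 1861 to 3100 at 12 h. The roots counts ranged from 25 to 134 at 0.25 h, 4 to 182 at 0.5 h, 0 (1091 at an unadjusted p under 0.05) to 122 at 1 h, 11 to 165 at 3 h, 128 to 333 at 6 h and 397 to 1123 at 12 h. The interaction counts ranged from 923 to 1840, 1205 to 2279, 1732 to 2841 and 679 to 1550 at 0.25, 0.5, 1 and 3 h. Of 1152 values of named genes and lists with 1 array left out, 1076 kept their call and 76 lost it. The 1152 include 21 genes of shoots against roots in each of these fits, which compare all arrays of the 2 tissues. The share kept is thus not that of the changes against 24 h. Totals of 159 and 152 below include such genes too. The calls kept numbered 157 of 159 after quantile normalization, 146 of 159 with log2(signal + 1) and 157 of 159 with no filter. They numbered 152 of 152 with the stricter filter and 157 of 159 without trend and robust. With only the arrays of the same tissue 117 of 135 were kept, and with the block 154 of 159. With 0.25 h as the reference 74 of 112 kept their call, 28 lost it and 10 changed sign, with the mean of 3, 6 and 12 h these were 58, 9 and 2 of 69, and 4 of 9 list calls held with an estimated correlation.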

Other observations

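Of the tests below, those on warmth and on a single aberrant array, with their bounds, and the gene families, were chosen only after the data were seen. Cytochrome P450 genes were lower in shoots than at 24 h more often than other genes at 0.25, 0.5 and 1 h. Of 14 measured members 9 were lower at 0.25 h, 11 at 0.5 h and 9 at 1 h, with median log2 changes of -0.78, -0.97 and -0.85. Most belong to the CYP71B group, of which CYP71B36 stood at -1.30, -1.5 and -2.08 and CYP71B23 at -0.97, -1.33 and -1.44. Fisher's exact test (one-sided, against the other genes among 8878, adjusted over 312 tests of 13 families) gave adjusted p-values of 0.00121, 1.47e-05 and 0.0102. At 3, 6 and 12 h 4, 2 and 5 were lower, with medians of -0.41, -0.39 and -0.15 (adjusted p = 0.49, 1 and 0.12); whether the early and late changes differ was not tested. Members of this group are similar in sequence, so their probe sets can share signal and are not independent. None of the 14 is named in the report or on a list. The reference here is the 24 h shoot arrays, which stood apart in RNA quality. The family was not retested with 1 of them left out or with another reference. Of the U-box ubiquitin ligases 5 of 8 were higher at 0.25 h and at 0.5 h, but these include genes of the rapid stress list; of the 5 members not already named 3 and 2 were higher (adjusted p = 0.253 and 0.801 among 8756 genes), so no excess of the family beyond the genes named was shown. After quantile normalization the P450 genes lower numbered 8, 10 and 9, in the same direction; at 3, 6 and 12 h 4, 6 and 5 P450 genes were then lower.

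Transcripts of plastid genes were lower in roots at 0.5 h than at 24 h in 19 of 69 measured cases, against 0.114% of the other genes (adjusted p = 3.26e-32 by the same test), with a median change of -0.60. At 3 h 4 of 69 were lower (adjusted p = 0.000766), with a median of -0.37. Without the genes already named by the rule, which prompted the question, 14 of 64 were lower at 0.5 h (adjusted p = 2.59e-23) and 3 of 64 at 3 h (adjusted p = 0.0046). These transcripts share their processing and vary together, so the p-values overstate the evidence. After quantile normalization 24 and 12 of the 69 were lower at these times. The photosynthesis list lay at medians of -0.32 and -0.20 at 0.5 and 3 h in roots and did not pass (camera adjusted p = 0.0906 and 0.349). Without roots 0.5 h replicate 2 the roots count at 0.5 h was 4 probe sets in all.

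At 12 h in roots the small heat shock genes had a median change of 3.26, and fermentation and low-oxygen genes rose with them. PDC2 stood at 2.64 ± 0.26, AT2G17850 at 2.86 ± 0.55 and AT3G29970 at 3.08 ± 0.53. In roots the small heat shock genes also lay above 24 h at 3 h (1.23 to 2.13) and 6 h (0.89 to 1.46). At these 2 times PDC2 stood at 1.79 and 1.58, AT2G17850 at 1.26 and 0.20 and AT3G29970 at 0.78 and -0.47. PDC2 was also higher in shoots at 12 h, by 1.80 (limma adjusted p = 4.53e-05). Warmth reaching the whole plant predicts a rise of the same heat shock genes in shoots, where their median was -0.31. A single aberrant 12 h root array as the cause predicts that the lower of both arrays keeps little of the change. In the 8 genes of the pattern it kept a median of 92.3% (88.8 to 97.0%), at least 2.29 above the 24 h mean. It kept as much in the 3 genes that the rule for large changes did not choose, but these too had passed the test on the same arrays. For these 8 genes both arrays thus carried the change. The genes were picked by their changes in these same arrays, and passing the test favours genes whose arrays agree. This outcome was thus partly settled beforehand, and the other calls at 12 h are not covered. Without roots 12 h replicate 1 HSP17.6C, AT2G29500, AT1G52560 and AT5G10040 kept changes of 3.27, 3.29, 2.66 and 2.74 but lost their calls (adjusted p = 0.053, 0.0649, 0.0625 and 0.103; AT5G10040 also without roots 24 h replicate 1, 0.0538, or 2, 0.0616). Low oxygen in the roots is a candidate explanation that these data do not settle: in a list of 30 low-oxygen genes written from memory after the pattern was seen, the 10 measured members not seen first had a median change of 1.24 with 5 of 10 called higher (camera adjusted p = 4.72e-07 over 12 comparisons), but adjusted p = 0.228 with an estimated correlation, which ends the call. The same members had medians of 1.28 at 1 h (adjusted p = 1.82e-10, and adjusted p = 0.146 with an estimated correlation) and 0.64 at 3 h (adjusted p = 1.02e-05 and 0.258), with 0 of 10 called at either time; whether the times differ was not tested.

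The overlap of shoots and roots calls was 2.85 times that of independent lists at 3, 6 and 12 h (419 against 147, exact 95% Poisson interval of the ratio 2.58 to 3.13) and 0.986 times at 0.25, 0.5 and 1 h (16 against 16.2, interval 0.564 to 1.60). The intervals treat probe sets as independent and are too narrow. The spread pooled over both tissues can also raise the overlap, which was not recomputed with a separate fit per tissue. A state of the 24 h plants shared by both tissues, as the whole cause, predicts that the overlap vanishes without the 24 h arrays. With 0.25 h as the reference it was still 2.7 times that of independent lists at 6 and 12 h, with 687 shared calls. The overlap thus did not need the 24 h arrays. The 0.25 h plants are again a reference common to both tissues, so a part played by a shared reference state stays open. Time of day may account for it: the 72 probe sets higher at 6 h in both tissues had a median change of -0.092 in shoots and -0.081 in roots at 0.25 h, near the 24 h level, but a slow response to wounding predicts the same, so these cannot be told apart without unwounded plants of each hour.

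For shoots against roots, 100 splits regrouped the 4 arrays of each time point 2 against 2. Only 1 of the 100 splits, the real one, gave as many as 14340 calls, and the highest of the others gave 10031. Splits that keep most arrays in place hold part of the tissue difference. Shoots and roots differ in most genes measured, and the other splits mix them within groups. The outcome was thus all but settled beforehand and only checks the tissue labels.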
